A study of Mus musculus with 9 samples.

How the data were processed

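Gene expression was measured in 9 samples of mouse pre-B cells null for IRF4 and IRF8, 3 in high IL-7, 3 in low IL-7 and 3 in high IL-7 with IRF4 put back. Per the labels' protocols, total RNA was extracted with Trizol and a column, labelled with biotin and hybridised to Affymetrix mouse expression arrays by the maker's standard protocols. Groups and replicate numbers were taken from the sample titles. The labels give the IL-7 amounts as 5 and 0.25 ng per volume but disagree on the volume.

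The authors deposited a single table of linear intensity values, 1 per probe set and array, for 45101 probe sets. How probe sets were summarised, scaled or filtered, and with what software, is not given in the sources used here. The values ran from 0 to 24761.9 and the array medians from 139.7 to 151.3, a range of 0.12 on the log2 scale, which is under the limit of 0.2 set for adding a normalization, so none was added. Every column of the table belonged to a sample, and no column was left out. No detection p-values were in the table, so whether a probe set stood above background was not known, and only the filter below guards against dim probe sets. That filter is on the mean of all arrays, and for Bcl2, Btla, Col3a1, Diras2, Fcmr, Gm266, Gpr18, Hmga2, Igkv8-30, Lta, Mc1r, Ms4a1, Pdgfra, Prdm1, Prf1 and Rbm24 at least 1 group lay below it, so the sizes of their changes depend on the added pseudocount. Replicates correlated with r from 0.978 to 0.995 and shared at most 2 identical values, so all 9 arrays were counted separately. No batch is given in the sources used here.

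Gene names came from the platform annotation supplied with the table: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, besides 64 control probe sets. Of the symbols, 34754 were matched by Entrez identifier to a RefSeq gene table of the assembly GRCm38.p6, which changed 0 of them. That table was used only for names and for which genes neighbour each other, and no coordinates are given, since the build behind the arrays' annotation is not given in the sources used here. Probe sets without a single symbol were left out of the gene tests.

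The following choices were fixed before the data were examined: the groups, the comparisons, the test, the filter, the 29 gene lists, the rule for named genes and most alternatives. Values were taken as log2(intensity + 16). Control probe sets were left out, probe sets were kept when their mean over the 9 arrays was at or above the 40th percentile of all probe sets (an intensity of 106.5), and the probe set with the highest mean stood for its gene, which left 12827 genes, 5757 of them with more than 1 probe set above the filter. Where probe sets of a gene named here disagreed in a way that bears on its call, this is said beside it. limma 3.58.1 in R 4.3.3 was used to fit group means over all 9 arrays (lmFit), so that the groups share 1 estimate of the spread, and moderated tests with a trend (eBayes), and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Irf4 and Irf8 probe sets, and those of Mycn, Bmf and the kappa segments, which were looked at after their values were seen, were adjusted over all probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

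Genes named in the text were chosen by a fixed rule: in each comparison the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between groups, up to 4 members of each list with the smallest p, all members of the recombination, surrogate light chain, light chain and STAT5 lists, 14 genes named in advance, and the 6 leading genes each way among those called in both comparisons against high IL-7, in the same and in opposite directions. Of the 29 lists, 27 had the 3 or more tested genes needed for camera, limma's set test, which was run with a preset correlation between genes of 0.01 and, as an alternative, with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists cover B cell development, signalling, cell cycle, metabolism, stress and markers of other cell types. Over the 3 comparisons 39 list calls were made with the preset correlation and 3 held with an estimated correlation.

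The comparisons against high IL-7 share their control arrays, so 100 simulations drew unchanged groups against those arrays. They give the overlap, correlation and covariance that arise with no effect, for genes drawn independently and arrays without pairing. The procedure was first tested on simulated data. Among 200 genes of 12827 given a known change, the low IL-7 comparison recovered 52.2% of those changed by 0.5, 89.6% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 10 other genes among its 171 calls. The IRF4 comparison against high IL-7 recovered 61.2%, 91% and 98.5%, with 5 others among its 172 calls. These genes were drawn independently and with the same spread in every array, so the shares need not hold for the real arrays.

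Low and high IL-7 share replicate numbers in the labels. The deviations from the group means of same-numbered arrays correlated across genes with r = 0.538, 0.377 and 0.281, all above the limit of 0.1 for pairing, though low IL-7 replicate 3 correlated more with high IL-7 replicate 2 (r = 0.341). So the numbers were taken to pair the arrays in that comparison, and a fit with the replicate number as a block was an alternative. The block was fitted over all 9 arrays, so it also held the IRF4 arrays, whose numbers did not pair them with the others. A block fit in the 6 paired arrays alone gave only a count of genes. The values of the fit over all 9 arrays stand beside a result of low against high IL-7 where they change a call. For the comparisons with IRF4 mainly the counts of calls are given.

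The alternatives tried were quantile normalization, scaling of each array to its 75th percentile, no filter, a filter at the 60th percentile, the replicate block, no variance trend, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, array weights, pseudocounts of 1 and 64, only the 6 arrays of the groups compared, a 2-fold threshold and leaving out each array in turn. Added after seeing the data were the mean of the stromal list as a covariate, leaving out the 2 arrays with low 18S signal, a block fit in the 6 paired arrays alone, the scalings for the lists, and high IL-7 arrays divided between the 2 comparisons that share them. Leaving out an array leaves 2 in its group, and the spread is still pooled over all groups.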

Results

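Total RNA of mouse pre-B cells, the B lymphocyte precursors that rearrange immunoglobulin light-chain genes, was measured on 9 expression arrays. All cells carried null alleles of IRF4 and IRF8, transcription factors of the interferon regulatory family. In 3 arrays the cells grew in high IL-7, a cytokine that drives the survival and division of B cell precursors, in 3 they grew in low IL-7, and in 3 they grew in high IL-7 after IRF4 had been put back. The source labels give the IL-7 amounts as 5 and 0.25 ng. The labels disagree on whether this is per millilitre or per microlitre, so no concentration is stated here. The array medians lay between 139.7 and 151.3 intensity units. Nothing in the labels says that the 3 arrays of a group came from separate cultures or animals, so all p-values measure the spread between these arrays only, which may be technical, and their number limits the precision. The first principal component held 62.3% of the variance and set the 3 low IL-7 arrays, at 34.96 to 39.54, apart from the other 6, at -23.18 to -16. All changes below are on the scale of log2(intensity + 16), which understates the change of dim genes, with n = 3 arrays per group and limma's adjusted p.

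Irf4 was read by 2 probe sets, which went opposite ways when IRF4 was put back. The dimmer probe set stood at 8.17 ± 0.44 (SD, n = 3) in high IL-7, 8.21 ± 0.15 in low IL-7 and 10.63 ± 0.63 with IRF4, a rise of 2.45 (SE 0.28, 5.48-fold, adjusted p = 0.000861 over all probe sets) that was seen in all 3 IRF4 arrays. The brighter probe set stood at 12.33 ± 0.15, 12.91 ± 0.08 and 11.93 ± 0.12. It rose by 0.57 in low IL-7 (adjusted p = 0.000502) and fell by 0.40 with IRF4 (adjusted p = 0.0438). The call of this fall was lost without a variance trend (adjusted p = 0.085) and with the replicate number as a block (adjusted p = 0.0613). It was also lost without any 1 of 7 arrays, all but high IL-7 replicate 2 and IRF4 replicate 3, with an adjusted p of up to 0.159. The brighter Irf8 probe set stood at 11.49 ± 0.12, 11.92 ± 0.10 and 11.21 ± 0.33. These probe sets may lie outside the deleted parts of the 2 genes, so their signal in null cells checks nothing about the knockout. The rise of the dimmer probe set fits the label of the group given IRF4.

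Low IL-7 was compared with high IL-7 to find which genes respond when the cytokine falls. Rag1 and Rag2, which together encode the recombinase that cuts immunoglobulin genes, rose by 4.67 (SE 0.25) and 3.37 (SE 0.12), which is 25.4-fold and 10.3-fold. Il7r, the receptor for IL-7 itself, rose by 2.83 (SE 0.11), and Myc and Ccnd2, which drive cell growth and entry into the cell cycle, changed by -2.66 (SE 0.17) and -3.03 (SE 0.10). In all, 4783 of 12827 genes changed, 2278 up and 2505 down, and 854 of them changed at least 2-fold, 341 up and 513 down. The other large rises were those of Bmf, a pro-apoptotic BCL2 relative (4.08, SE 0.25), Rbm24, an RNA-binding protein (3.57), Dntt, which adds nucleotides at recombination joints (3.28, SE 0.53), Lgr5 (3.13), Hmga2, a chromatin protein (3.10), and Cpm, a carboxypeptidase (3.07). For Bmf, the rise came from 1 of 3 probe sets, and the others changed by 0.19 (adjusted p = 0.477) and -0.01 (adjusted p = 0.976). The other large falls were those of Tubb3, a tubulin (-3.72), Mc1r, a melanocortin receptor whose gene lies beside Tubb3 (-3.09), Trgv4, a T cell receptor segment (-2.98), Nefh, a neurofilament (-2.86), Gm266 (-2.79) and Asns, asparagine synthetase (-2.72). The arrays of the 2 groups did not overlap for 6428 genes, 50.1%, against the 10% that chance gives for 3 against 3. Array weights raised the count to 8266.

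**Figure D1:**
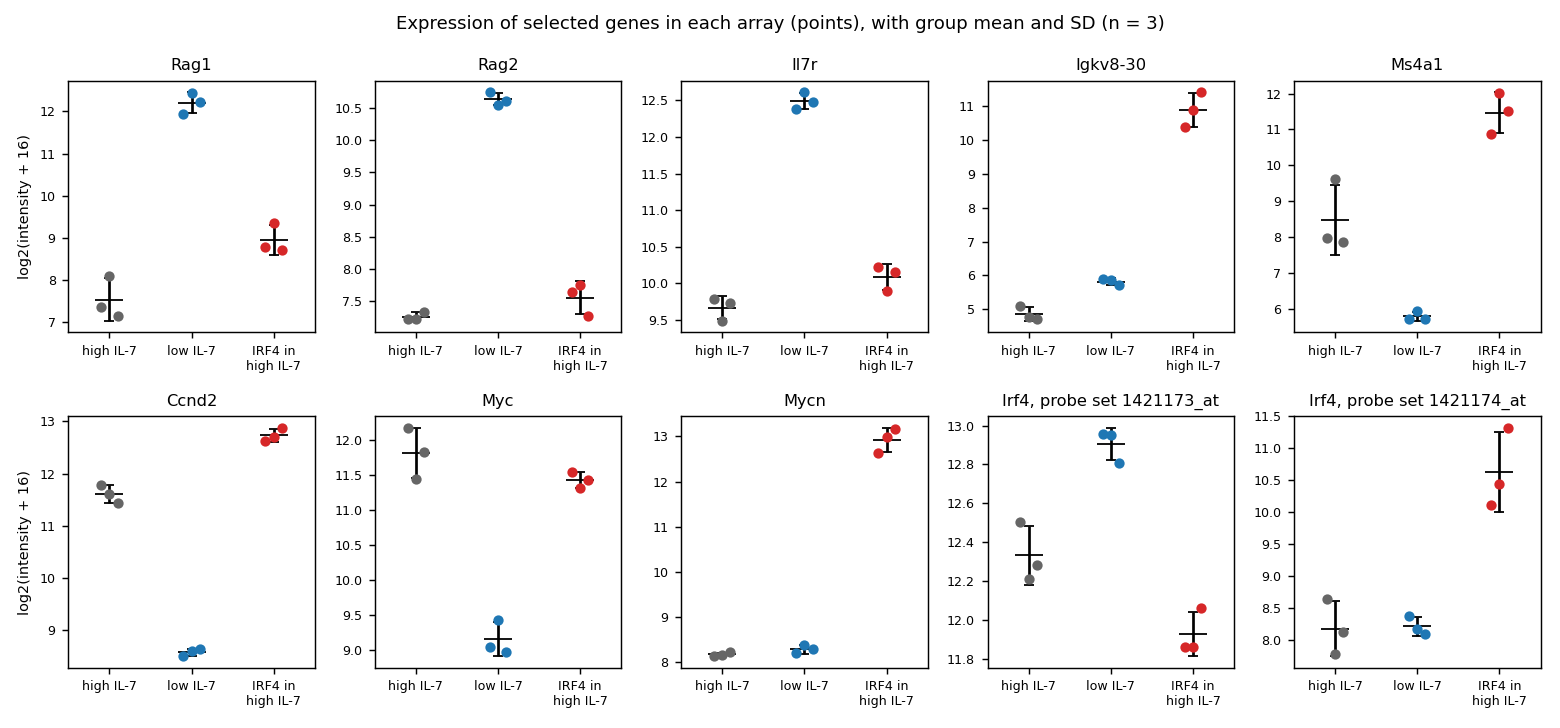
Each panel plots 1 gene or probe set, with log2(intensity + 16) on the vertical axis and the 3 groups on the horizontal axis; each point is 1 array, the long horizontal line is the group mean and the bars are the SD (n = 3). Rag1, Rag2 and Il7r are highest in low IL-7, Igkv8-30 and 1 of 3 Mycn probe sets are highest with IRF4, and Ms4a1 and Ccnd2 move in opposite directions in low IL-7 and with IRF4.

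Of the 13 genes of the V(D)J recombination machinery that were tested, 5 rose and 2 fell in low IL-7, with the same counts adjusted over the list alone. The members that rose were Rag1, Rag2, Dntt, Lig4, the ligase that seals the joints (2.03, SE 0.12), and Xrcc6 (1.46). Xrcc5, whose product pairs with that of Xrcc6 to form the Ku dimer, changed by -0.99, and Atm by -0.48. As a whole the list, with a median of 0.15, did not pass camera, the set test (camera adjusted p = 0.0656). Among 16 genes of the pre-B cell receptor and its proximal signalling, 10 rose and 1 fell, again the same adjusted over the list alone, with Blk (1.98), Prkcb (1.48), Blnk, an adaptor (1.42), Vpreb3 (1.11) and Syk, a kinase (1.01), among the rises. The list passed camera (median 0.30, adjusted p = 0.000575) but not when the correlation between genes was estimated (adjusted p = 0.338 with an estimated correlation). Of the 2 surrogate light chain genes tested, Vpreb1 rose by 0.25 (SE 0.07), while Igll1 changed by 0.14 (adjusted p = 0.226, or 0.0206 with the replicate number as a block). Among 5 immunoglobulin light-chain probe sets with a single gene name, 2 rose, and 3 did when adjusted over the list alone: Igkv8-30, a kappa variable segment, rose by 0.95 (SE 0.21), with both groups below the intensity of the filter and so not known to be above background, and Igk by 0.34, whose call was lost with the replicate number as a block (adjusted p = 0.0504) and without any low IL-7 array, high IL-7 replicate 2 or 3 or IRF4 replicate 2 (adjusted p up to 0.143). A dimmer Igk probe set than the one tested changed by -0.21 in low IL-7 (adjusted p = 0.114 over all probe sets). The list median was 0.31 (camera adjusted p = 0.258).

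B-lineage transcription factors rose broadly in low IL-7: 20 of 29 rose and 1 fell, with the same counts adjusted over the list alone. Bach2 rose by 1.73 (SE 0.08), Foxo1 by 1.49 (SE 0.08), Lef1 by 1.15, Myb by 0.99, Spib by 0.93 and Ikzf1 by 0.47, and Bcl11a changed by -0.84. This list passed camera with the preset correlation (median 0.51, adjusted p = 1.83e-07) and with an estimated correlation (adjusted p = 0.0211). It was the only list of 27 to do so in this comparison. Of 19 FOXO target genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with S1pr1, a receptor for lymphocyte exit (1.21), and Ccng2 (1.54) beside Rag1, Rag2 and Il7r. Their median was 0.87 (camera adjusted p = 1.28e-06, and adjusted p = 0.123 with an estimated correlation). The early B progenitor list shares Dntt and Lig4 with the recombination list. Among its 12 tested genes 9 rose and none fell, the same adjusted over the list alone, including Cd93 (2.52), Id2 (1.44) and Spn (0.67). Their median was 0.79 (camera adjusted p = 0.000123, and adjusted p = 0.0875 with an estimated correlation). Of 13 STAT5 target genes, the genes that IL-7 signalling is known to switch on, 3 rose and 6 fell (4 and 8 adjusted over the list alone). The falls included Cish (-1.98, SE 0.12), Ccnd2, Myc, Socs2 (-0.65), Osm (-0.56) and Pim1 (-0.40), the rises were Bcl2l1 (0.65), Bcl2 (0.38) and Mcl1 (0.35), all of which protect cells from apoptosis. The median of the 13 was -0.56 (camera adjusted p = 0.0606). Prdm1, a driver of plasma cell fate, rose by 2.86 (SE 0.13) and Xbp1, a regulator of secretion, changed by -1.30. Over the 16 tested genes of the plasma cell programme 4 rose and 7 fell, the same adjusted over the list alone. Their median was -0.02 (camera adjusted p = 0.492).

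Markers of maturing B cells went both ways in low IL-7. Of 16 tested, 5 rose and 3 fell (6 and 3 adjusted over the list alone): Fcrla (1.47) and Cd72 (1.13) rose, and Ms4a1, which encodes CD20, Btla and Tnfrsf13c, the BAFF receptor, changed by -2.69 (SE 0.41), -1.77 and -0.84. Fcmr, at 0.52 (adjusted p = 0.0542), passed with the replicate number as a block (adjusted p = 0.0113). The list median was 0.10 (camera adjusted p = 0.382). Of 9 MHC class II genes, which present antigen, H2-Ob rose by 1.99 (SE 0.18) and none fell, the same adjusted over the list alone (median 0.09, camera adjusted p = 0.689), and Cd74 changed by -0.59 (adjusted p = 0.088, or 0.0289 with the replicate number as a block). Among 14 chemokine receptors and adhesion genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.32, camera adjusted p = 0.106), with Itga4 (1.60) and Cxcr4, the receptor that holds precursors in bone marrow (1.17, SE 0.18), among the rises and Cxcr5 among the falls (-0.92). Of 16 NF-kB target genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.09, camera adjusted p = 0.24), with Nfkbia (1.38) and Tnfaip3 (0.97) up and Lta (-1.62) down.

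Genes of growth and metabolism fell together in low IL-7. All 30 ribosome biogenesis genes fell, the same adjusted over the list alone, with Nop16 at -2.09 (SE 0.09), Polr1b at -1.95 (SE 0.10) and Npm1 at -0.60. Their median was -1.37 (camera adjusted p = 5.96e-24, and adjusted p = 0.0875 with an estimated correlation). Of 18 genes of glycolysis and glucose uptake 16 fell and 1 rose, the same adjusted over the list alone: Hk2, hexokinase, changed by -2.23 (SE 0.10), Pkm by -1.66 and Slc2a1, a glucose transporter, by -1.45. Their median was -1.05 (camera adjusted p = 3.08e-08, and adjusted p = 0.233 with an estimated correlation). Of 23 genes of amino acid starvation and the integrated stress response 17 fell and none rose (18 and none adjusted over the list alone), including Asns, Shmt2 (-2.04) and Slc7a1, an amino acid transporter (-1.89). Their median was -1.18 (camera adjusted p = 7.21e-08, and adjusted p = 0.298 with an estimated correlation). Of 20 cholesterol biosynthesis genes 15 fell and none rose, the same adjusted over the list alone, including Fdps (-1.56) and Lss (-1.02). Their median was -0.66 (camera adjusted p = 6.52e-06, and adjusted p = 0.385 with an estimated correlation).

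Cell cycle genes moved in different directions in low IL-7. Of 29 genes of mitosis and G2/M 22 rose and none fell (25 and none adjusted over the list alone), among them Cenpf (0.93, SE 0.08), Nusap1 (0.78), Ccnb2 (0.67) and Mki67 (0.58). Their median was 0.43 (camera adjusted p = 3.08e-08, and adjusted p = 0.233 with an estimated correlation). Of 28 genes of DNA replication and G1/S 2 rose, Rrm2 (0.50) and E2f2 (0.72), and 4 fell (2 and 3 adjusted over the list alone), with Mcm3 (-0.51) and Mcm10 (-0.49) among the falls. Their median was -0.04 (camera adjusted p = 0.732). Of 14 cell cycle inhibitors 9 rose and 1 fell, the same adjusted over the list alone, with Btg1 (1.51), Cdkn2c (1.47), Cdkn2d (1.36) and Rb1 (1.07) rising. Their median was 0.94 (camera adjusted p = 1.74e-05, and adjusted p = 0.0676 with an estimated correlation). In the BCL2 family of 13 genes, 5 rose and 2 fell, the same adjusted over the list alone: Bmf and Bcl2l1 rose and Bid fell (-1.36). Bak1 also fell (-0.91), but not with the replicate number as a block (adjusted p = 0.0621), without a variance trend, or without high IL-7 replicate 1 or any low IL-7 array (adjusted p up to 0.144). Bcl2l2 rose (0.41), but not without any low IL-7 array or replicate 2 or 3 of the other groups (adjusted p up to 0.164). The list median was 0.01 (camera adjusted p = 0.354). Of 15 p53 target genes 4 rose and 1, Aen (-0.81), fell, the same adjusted over the list alone, with Trp53inp1 (1.51) and Btg2 (1.47) rising. Their median was 0.11 (camera adjusted p = 0.385). Over the 27 lists, 10 passed camera with the preset correlation in this comparison, but in other splits of the same 6 arrays up to 13 did.

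Genes of other cell types were measured beside these. The mean of 19 stromal and fibroblast markers was 9.14 ± 0.81 (SD, n = 3) in high IL-7, 8.36 ± 0.47 in low IL-7 and 8.40 ± 0.91 with IRF4, and single arrays ranged from 7.75 to 9.86, so it varied within groups as widely as between them. In low IL-7, 3 of the 19 fell and none did when adjusted over the list alone. The median of the 19 was -0.48 (camera adjusted p = 0.385). The 3 were Col3a1, a collagen (-2.74, SE 0.87), Pdgfra (-2.66, SE 0.76) and Col6a1 (-1.99, SE 0.69). With the replicate number as a block, the adjusted p of Col3a1 was 0.0522 and that of Col6a1 0.0716, and without low IL-7 replicate 1, 2 or 3 or high IL-7 replicate 2 or 3 it rose to at most 0.0991 for Col3a1, 0.0625 for Pdgfra and 0.139 for Col6a1. Of 10 T cell markers 1, Thy1, passed (-0.37), and lost its call without high IL-7 replicate 1 or 2 or low IL-7 replicate 2 or 3 (adjusted p up to 0.158). Cd8a, at 0.29 (adjusted p = 0.0533), passed with the replicate number as a block (adjusted p = 0.0366). None passed adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.689). Of 13 myeloid markers Fcer1g rose (1.49) and Ctss fell (-0.72), the same adjusted over the list alone. Their median was 0.04 (camera adjusted p = 0.689). Of 8 erythroid and megakaryocyte markers 2 fell, the same adjusted over the list alone: Car2 (-0.71) and Pf4 (-0.32), the latter not without high IL-7 replicate 3 (adjusted p = 0.0565). Their median was 0.03 (camera adjusted p = 0.689). Of 8 dendritic and natural killer cell markers 1 rose and 1 fell, the same adjusted over the list alone: Prf1 (0.38), which lost its call without high IL-7 replicate 1 or 3 or low IL-7 replicate 2 or 3 (adjusted p up to 0.0658), and Bst2 (-1.64). Their median was 0.09 (camera adjusted p = 0.732). The mean of the last 2 lists was below 0. Of 26 interferon-stimulated genes 1 rose, Gbp2 (0.89), and 3 fell, the same adjusted over the list alone. Their median was 0.01 and their mean -0.15 (camera adjusted p = 0.689). The 1 sex-linked gene tested, Xist, rose by 0.45 (SE 0.07), the same adjusted over the list alone. As signs of RNA quality, the 18S control signal was 6.53 in high IL-7 replicate 1 and 6.41 in IRF4 replicate 3 against 7.70 to 8.49 in the other arrays. The log2 ratio of 3 prime to 5 prime Actb signal was 0.46 ± 0.16 (SD, n = 3) in high IL-7, 0.53 ± 0.07 in low IL-7 and 0.45 ± 0.11 with IRF4. That of Gapdh was 0.07 ± 0.05, 0.06 ± 0.01 and 0.08 ± 0.06. In high IL-7 replicate 1 and IRF4 replicate 3 the Actb ratios were the lowest (0.28 and 0.33) and the Gapdh ratios the highest (0.13 and 0.14). The ratios of these arrays thus went opposite ways, so their low 18S signal is not shown to mean poorer RNA.

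**Figure D2:**
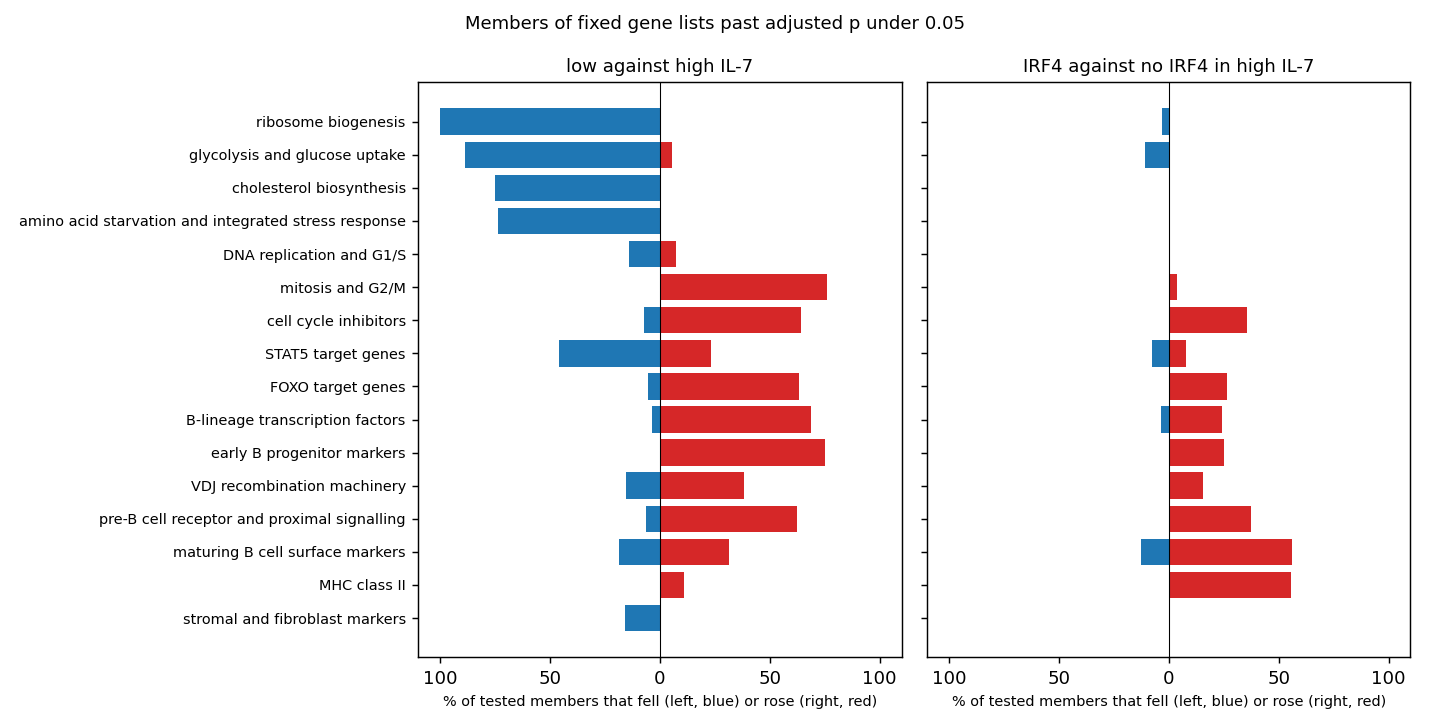
Bars give the percentage of the tested members of 16 fixed gene lists that fell (left, blue) or rose (right, red) past an adjusted p of 0.05, in low against high IL-7 (left panel) and with IRF4 against no IRF4 in high IL-7 (right panel). All 30 ribosome biogenesis genes fell in low IL-7 and 1 fell with IRF4, while 5 of 9 MHC class II genes rose with IRF4 and 1 rose in low IL-7.

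IRF4 in high IL-7 was compared with high IL-7 alone, which holds IL-7 fixed and asks what IRF4 changes. The sample titles name no group handled the same way without IRF4. The means of putting it back thus cannot be told apart from IRF4 itself. Igkv8-30, the kappa variable segment, rose by 6.04 (SE 0.21), from 4.87 ± 0.21 to 10.91 ± 0.50 (SD, n = 3). Its probe set can match several transcripts and passed the filter through the IRF4 arrays alone, so the size of the rise depends on the added 16 and the signal is not assigned to that segment alone. The invariant chain gene Cd74 rose by 3.09 (SE 0.25), Ms4a1 by 2.97 (SE 0.41) and H2-Aa, an MHC class II chain, by 2.85 (SE 0.24). In all, 376 of 12827 genes changed, 246 up and 130 down, and 105 changed at least 2-fold, 82 up and 23 down. Other large rises were those of 1 Mycn probe set (4.75, SE 0.12), Lsp1, a leukocyte actin-binding protein (3.12), Fcrla (2.68) and Gpr18 (2.60). Mycn encodes a MYC relative and only 1 of its 3 probe sets rose: the other 2 changed by -0.11 (adjusted p = 0.841) and -0.06 (adjusted p = 0.919). In low IL-7 the first of these fell by 1.47 (adjusted p = 5.95e-05), while the probe set that rose with IRF4 was at 0.11 (adjusted p = 0.596). What sequence each of them reads is not given in the sources used here, so the rise is not assigned to Mycn. The large falls were those of Ifitm1 (-1.83, SE 0.21), Scn4b, a sodium channel subunit (-1.61), Fcer1g (-1.40) and Tubb3 (-1.37). Nckap1 (-1.73), Mc1r (-1.67), Nol4l (-1.53) and Kcnk1 (-1.38) completed the 8 largest falls. Each of these 4 lost its call without certain arrays, Mc1r without IRF4 replicate 3 (adjusted p = 0.0505), Nol4l without IRF4 replicate 2 (0.0524), and Nckap1 without replicate 2 or 3 of either group (up to 0.0874). Kcnk1 lost it without these, high IL-7 replicate 1 or low IL-7 replicate 3 (up to 0.148). The arrays did not overlap for 2692 genes, 21%, against the 10% of chance. The count was 191 without IRF4 replicate 2, 204 without high IL-7 replicate 3, 615 without IRF4 replicate 1, 222 when the low IL-7 arrays were left out and 3248 with array weights, so its size depends on single arrays. So does the balance of rises: 267 genes rose and 348 fell without IRF4 replicate 1, 201 and 58 without IRF4 replicate 3, and 1581 and 1667 with array weights.

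Igkv8-30 and part of the pre-B cell receptor list rose with IRF4, while 11 of 13 genes of the recombination machinery did not pass. Among 13 genes of the machinery 2 rose and none fell, the same adjusted over the list alone: Rag1 by 1.42 (SE 0.25, adjusted p = 0.0113) and Lig4 by 0.94 (SE 0.12). Their median was 0.03 (camera adjusted p = 0.0549). Rag2 changed by 0.30 (SE 0.12, adjusted p = 0.292). Of the 5 light-chain probe sets 1 rose, Igkv8-30, the same adjusted over the list alone. A dimmer Igk probe set than the one tested also rose, by 0.63 (adjusted p = 0.00422 over all probe sets). The median of the 5 was 0.17 and their mean 1.30 (camera adjusted p = 0.00218, and adjusted p = 0.197 with an estimated correlation). This set result rests on Igkv8-30, whose probe set passed the filter through the IRF4 arrays alone. It thus gives no support for a shift of the list as a whole. Neither surrogate light chain gene passed (Vpreb1 -0.15, adjusted p = 0.321; Igll1 -0.20, adjusted p = 0.308), but both fell when adjusted over the list alone. Of 16 genes of the pre-B cell receptor and its signalling 6 rose and none fell (9 and none adjusted over the list alone): Blk by 1.70, Pik3ap1 by 1.14, Syk by 0.98 (SE 0.14), Prkcb by 0.89, Vpreb3 by 0.76 and Cd79b by 0.47, the last not without IRF4 replicate 2 (adjusted p = 0.0599). Their median was 0.22 (camera adjusted p = 1.08e-06, and adjusted p = 0.197 with an estimated correlation). Blnk was at 0.18 (adjusted p = 0.164, or 0.0384 with 75th percentile scaling).

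Maturation and antigen presentation genes rose with IRF4. Of 16 maturing B cell surface markers 9 rose and 2, Cd72 (-0.51) and Cd9 (-0.64), fell (10 and 2 adjusted over the list alone). The rises included Ms4a1, Fcrla, Fcmr (1.57), Tnfrsf13c (1.37, SE 0.11), Cd52 (1.28) and Btla (1.35), whose call was lost without IRF4 replicate 2 or high IL-7 replicate 3 (adjusted p up to 0.0679). Their median was 0.56 (camera adjusted p = 1.9e-09, and adjusted p = 0.124 with an estimated correlation). Of 9 MHC class II genes 5 rose and none fell (8 and none adjusted over the list alone), with H2-Eb1 at 2.19 (SE 0.22) and H2-DMa at 1.08 beside Cd74 and H2-Aa. Their median was 0.95 (camera adjusted p = 1.1e-12, and adjusted p = 0.0882 with an estimated correlation). Among 29 B-lineage transcription factors 7 rose and 1 fell (11 and 4 adjusted over the list alone): Spib by 1.51 (SE 0.11), Bach2 by 1.03, Mef2c by 0.99, Ikzf1 by 0.74 (SE 0.06) and Bcl11a by 0.63 were among the rises (median 0.18, adjusted p = 0.000119), and this call held with an estimated correlation (adjusted p = 0.0473). Ikzf3 changed by 0.18 (adjusted p = 0.467) and Bcl6 by -0.19 (adjusted p = 0.68). Of 14 chemokine receptors and adhesion genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Ccr7 (1.47) and Cxcr4 (1.17, SE 0.18) rising. Their median was 0.11 (camera adjusted p = 0.0437, and adjusted p = 0.197 with an estimated correlation). Of 16 plasma cell genes 1 rose, Ell2 (1.69), and none fell (1 and 3 adjusted over the list alone). Their median was 0.00 (camera adjusted p = 0.611, with test and mean of opposite sign). Of 12 genes of the early B progenitor list 3 rose and none fell (4 and 1 adjusted over the list alone). The rises were those of Ly6d (2.15), Cd93 (1.70) and Lig4, a ligase gene also counted in the recombination list. The median of the 12 was 0.03 (camera adjusted p = 0.0261, and adjusted p = 0.197 with an estimated correlation). The chemokine receptor and adhesion call was lost without high IL-7 replicate 2 or 3 or IRF4 replicate 1 or 3 (adjusted p up to 0.0777). The progenitor call was lost without IRF4 replicate 1 or high IL-7 replicate 2 (adjusted p up to 0.0826).

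Genes of growth, metabolism and division showed few calls with IRF4. Ribosome biogenesis genes fell in 1 of 30, the same adjusted over the list alone, with median -0.14 (adjusted p = 1e-05, and adjusted p = 0.315 with an estimated correlation). The gene was Ppan (-0.33), whose call was lost without any single array (adjusted p up to 0.211). Of 18 genes of glycolysis and glucose uptake 2 fell and none rose (9 and none adjusted over the list alone): Slc2a1 (-0.53) and Hk2 (-0.45), which lost their calls without replicate 2 or 3 of either group, and Hk2 also without any low IL-7 array (adjusted p up to 0.0955 and 0.199). Their median was -0.35 (camera adjusted p = 1.15e-07, and adjusted p = 0.197 with an estimated correlation). None of 20 cholesterol genes (median -0.20, adjusted p = 0.00218, and adjusted p = 0.505 with an estimated correlation) and none of 23 stress response genes (median -0.21, adjusted p = 4.86e-05, and adjusted p = 0.343 with an estimated correlation) passed, and none did adjusted over the list alone. Of 29 mitosis genes 1 rose, the same adjusted over the list alone, Nusap1 (0.27), which lost its call without replicate 2 or 3 of any group or IRF4 replicate 1 (adjusted p up to 0.182). Their median was 0.09 (camera adjusted p = 0.00706, and adjusted p = 0.447 with an estimated correlation). None of 28 replication genes passed in either adjustment. Their median was 0.06 (camera adjusted p = 0.0437, and adjusted p = 0.661 with an estimated correlation). Single arrays decided 3 of these list calls: the cholesterol call was lost without high IL-7 replicate 1 or IRF4 replicate 3 (adjusted p up to 0.172) and the mitosis call without high IL-7 replicate 2 (adjusted p = 0.196). The replication call was lost without high IL-7 replicate 2 or 3 or any IRF4 array (adjusted p up to 0.0954). Cell cycle inhibitors rose in 5 of 14 and none fell (7 and 1 adjusted over the list alone), with Rb1 (1.09, SE 0.12), Btg1 (1.05) and Cdkn2d (0.84) among them (median 0.24, adjusted p = 1.08e-06), and this call held with an estimated correlation (adjusted p = 0.0473). Ccnd2 rose by 1.12 (SE 0.10), while Ccnd3 changed by 0.37 (adjusted p = 0.267) and Myc by -0.39 (adjusted p = 0.327).

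The remaining lists gave few calls with IRF4. Of 13 STAT5 target genes 1 rose, Ccnd2, and 1 fell (3 and 1 adjusted over the list alone; median 0.04, camera adjusted p = 0.0889); the fall was that of Cish (-0.54), lost without any single array but IRF4 replicate 1 (adjusted p up to 0.187). Of 19 FOXO target genes 5 rose and none fell (10 and none adjusted over the list alone), among them Ccr7 and Rag1 (median 0.30, adjusted p = 2.57e-07, and adjusted p = 0.117 with an estimated correlation), and Il7r was at 0.42 (adjusted p = 0.0889). Of 13 BCL2 family genes none passed (3 rose adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.0745). Of 15 p53 target genes Trp53inp1 rose (0.71; 2 and 1 adjusted over the list alone). Their median was 0.01 (camera adjusted p = 0.39). Of 16 NF-kB target genes 2 rose, the same adjusted over the list alone: Birc3 (0.64) and Nfkbie (0.54), the latter not without IRF4 replicate 2 or high IL-7 replicate 3 (adjusted p up to 0.0599). Their median was 0.09 (camera adjusted p = 0.0437, and adjusted p = 0.197 with an estimated correlation). The list call was lost without any 1 high IL-7 array or IRF4 replicate 1 or 3 (adjusted p up to 0.0968). Of 26 interferon-stimulated genes 1 rose, Ifi27l2a (1.91; 2 adjusted over the list alone; median 0.18, adjusted p = 0.0437, and adjusted p = 0.713 with an estimated correlation), and it lost its call without any single array but high IL-7 replicate 2 or IRF4 replicate 1 (adjusted p up to 0.155). The interferon list's mean was highest in high IL-7 replicate 2 (9.58) and IRF4 replicate 3 (9.89), and without the latter its median was -0.16 (adjusted p = 0.497). The list call was also lost without high IL-7 replicate 1 (adjusted p = 0.0842) or 3 (adjusted p = 0.823). None of 19 stromal markers passed in either adjustment, while their median was -0.75 (camera adjusted p = 0.00441, and adjusted p = 0.515 with an estimated correlation). This call was lost without high IL-7 replicate 2 (adjusted p = 0.188) or IRF4 replicate 2 (adjusted p = 0.079). T cell markers rose in 1 of 10, Cd2, by 2-fold, and 1 rose and 2 fell adjusted over the list alone. Their median was 0.03 (camera adjusted p = 0.99) and their mean had the other sign. Myeloid markers rose in 1 of 13, Ctss (1.29), and fell in 1, Fcer1g, the same adjusted over the list alone. Their median was 0.03 (camera adjusted p = 0.82) and their mean was below 0. Of 8 erythroid markers Car2 fell (-0.59), the same adjusted over the list alone (median 0.07, camera adjusted p = 0.611), and of 8 dendritic and natural killer cell markers none passed in either adjustment. Their median was -0.03 (camera adjusted p = 0.828). Xist was at -0.14 (adjusted p = 0.339). In this comparison 18 lists passed camera with the preset correlation, and up to 10 did in other splits of the 6 arrays.

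The title names convergent pathways, so the 2 responses were compared gene by gene. Tifa, a signalling adaptor, rose by 3.01 in low IL-7 and 1.92 with IRF4, Ifi209 by 2.59 and 1.76, Cd93 by 2.52 and 1.70, Cecr2 by 2.24 and 1.97, and Blk by 1.98 and 1.70 (SE 0.13 to 0.30). Diras2 was at 1.83 and 1.96, the second lost without high IL-7 replicate 3 or IRF4 replicate 3 (adjusted p up to 0.0707). Tubb3, Mc1r, Cst7, Cxcr5, Zfp783 and Shcbp1l led the genes that fell in both; the IRF4 calls of Cst7, Cxcr5 and Shcbp1l were lost without IRF4 replicate 2 or 3 (adjusted p up to 0.0907, 0.0644 and 0.116) and Shcbp1l also without high IL-7 replicate 2 or 3. Mc1r lost its IRF4 call without IRF4 replicate 3 (adjusted p = 0.0505). In all, 158 genes rose in both and 55 fell in both, 213 together, against 43.7, 25.4 and 69.1 for independent lists and 0 in 100 simulations of unchanged groups against the same high IL-7 arrays. Of the genes changed with IRF4, 56.6% changed the same way in low IL-7. Across genes, which are not independent replicates, the fold changes had a covariance of 0.042 against 0.00858 in the simulations, a difference of 0.0334, with r = 0.307 against 0.501 and 62.2% against 66.7% of genes with the same sign. The simulation leaves out real effects and draws each gene independently. Its count of 0 was thus nearly fixed in advance and gives the 213 no support. The independent lists leave out the shared arrays. With the high IL-7 arrays divided so that none was shared, 1 for one comparison and 2 for the other, the 6 divisions gave 55 to 142 genes changed the same way, each above its own value for independent lists, which ran from 15.7 to 52.1. The covariance was 0.013 to 0.0411, below the 0.042 with shared arrays in every division, and r was 0.0784 to 0.298. The count was 113 without IRF4 replicate 2, 112 without high IL-7 replicate 3 and 1897 with array weights.

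A smaller set of 47 genes changed in opposite directions, 31 up in low IL-7 and down with IRF4 and 16 the other way. Independent lists would give 71.1, but shared control arrays favour changes the same way. In the 6 divisions with none shared, 12 to 53 genes changed in opposite directions, against 17.3 to 56.4 for independent lists, fewer in 4 divisions and more in 2. Scn4b (2.45 and -1.61), Fcer1g (1.49 and -1.40), Slc7a7 (1.44 and -1.17), Eps8l2 (1.01 and -0.99) and Scin, an actin-severing protein (1.38 and -0.94), rose in low IL-7 and fell with IRF4. Zfp52 did so as well (1.53 and -0.96), but not without IRF4 replicate 2 or high IL-7 replicate 2 or 3 (adjusted p up to 0.0612). Ms4a1 (-2.69 and 2.97), Ccnd2 (-3.03 and 1.12), Tnfrsf13c (-0.84 and 1.37), Plek (-0.78 and 1.48) and Ctss, a lysosomal protease (-0.72 and 1.29), fell in low IL-7 and rose with IRF4.

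**Figure D3:**
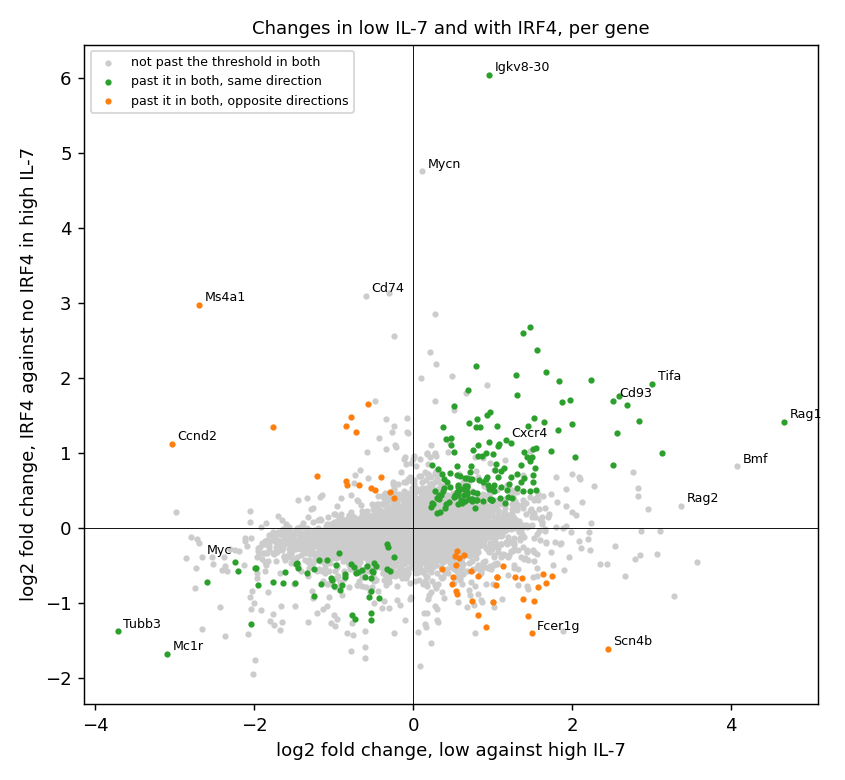
Each point is 1 of 12827 genes, with its log2 fold change in low against high IL-7 on the horizontal axis and with IRF4 against no IRF4 in high IL-7 on the vertical axis. Green points passed an adjusted p of 0.05 in both comparisons in the same direction (213 genes), orange points in opposite directions (47 genes), and grey points did not pass in both.

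The IRF4 arrays were then compared with the low IL-7 arrays, which tests whether the 2 responses differ. Ms4a1 was higher with IRF4 by 5.66 (SE 0.41), Igkv8-30 by 5.08 (SE 0.21), the Mycn probe set by 4.64, Ccnd2 by 4.15 (SE 0.10), Cd74 by 3.69, Lsp1 by 3.42, Trgv4 by 3.20 and Btla by 3.11. Dntt (-4.19, SE 0.53), Scn4b (-4.05), Rbm24 (-4.03), Cpm (-3.41), Sertad4 (-3.30), Maf (-3.26), Bmf (-3.26) and Rag1 (-3.25, SE 0.25) were lower with IRF4. Rag2 (-3.07, SE 0.12) and Il7r (-2.41) were also lower, while Cxcr4 (0.00, adjusted p = 1) and Syk (-0.03, adjusted p = 0.911) did not pass. In all, 4651 genes differed, 2386 higher and 2265 lower with IRF4, and 729 differed at least 2-fold, 371 higher and 358 lower. Of the 213 genes that changed the same way in both responses, 120 differed in size. The arrays did not overlap for 6152 genes, 48%, against the 10% of chance. Array weights raised the count to 7810.

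Growth and metabolism genes were higher with IRF4 than in low IL-7: all 30 ribosome biogenesis genes (median 1.18, camera adjusted p = 6.91e-23), 14 of 18 glycolysis genes with 2 lower (median 0.77, adjusted p = 2.14e-05), 15 of 23 stress response genes with 2 lower (median 0.95, adjusted p = 2.3e-05) and 12 of 20 cholesterol genes (median 0.52, adjusted p = 0.00126). The adjusted p with an estimated correlation was 0.161, 0.388, 0.447 and 0.605. So were 7 of 9 MHC class II genes, with 1 lower (median 1.05, adjusted p = 0.00405), and 7 of 13 STAT5 target genes (median 0.38, adjusted p = 0.0063), with adjusted p = 0.447 and 0.375 with an estimated correlation. Lower with IRF4 were 19 of 29 mitosis genes, with 1 higher (median -0.37, adjusted p = 3.12e-06), 12 of 19 FOXO target genes, with 2 higher (median -0.62, adjusted p = 0.00038), 8 of 12 early B progenitor markers, with 1 higher (median -0.74, adjusted p = 0.0031), 15 of 29 B-lineage transcription factors, with 4 higher (median -0.43, adjusted p = 0.00126), and 7 of 14 cell cycle inhibitors, with 1 higher (median -0.45, adjusted p = 0.00457). The adjusted p of these 5 with an estimated correlation was 0.36, 0.306, 0.204, 0.161 and 0.204. Adjusted over the list alone, the counts of higher and lower genes for these 11 lists were, in the order given, 30 and 0, 14 and 2, 15 and 2, 13 and 0, 7 and 1, 8 and 1, 1 and 20, 2 and 12, 2 and 8, 4 and 16, and 1 and 7. These 11 were the lists that passed camera here, and up to 11 did in other splits of the 6 arrays.

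The other lists did not pass camera in this comparison. Recombination machinery genes were higher with IRF4 in 3 and lower in 5 of 13, maturing B cell markers in 9 and 2 of 16, plasma cell genes in 8 and 4 of 16, replication genes in 7 and 4 of 28, pre-B cell receptor genes in 0 and 6 of 16, chemokine receptor and adhesion genes in 1 and 5 of 14, NF-kB target genes in 2 and 4 of 16, p53 target genes in 1 and 2 of 15 and BCL2 family genes in 2 and 2 of 13. Interferon-stimulated genes were higher in 3 and lower in 0 of 26, light-chain probe sets in 1 and 0 of 5, stromal markers in 0 and 2 of 19, T cell markers in 1 and 0 of 10, myeloid markers in 1 and 2 of 13, erythroid markers in 1 and 0 of 8, and dendritic and natural killer cell markers in 1 and 1 of 8. Both surrogate light chain genes and Xist were lower with IRF4. The median differed in sign from the mean or the test for the recombination, light-chain, stromal and dendritic and natural killer cell lists. Adjusted over the list alone, the counts differed from these for 3 of the lists that did not pass: 8 and 4 for replication, 2 and 6 for chemokine receptors and adhesion and 2 and 0 for interferon-stimulated genes.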

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

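The tests of the probe sets below were chosen after the results on named genes were seen. Probe sets that name no single gene stood outside the gene tests and gave signal. Of 4302 such probe sets above the filter, 620 name several genes and 3682 name none. In low against high IL-7, 1219 of them changed, 815 up and 404 down. With IRF4 against high IL-7, 72 changed, 31 up and 41 down, and with IRF4 against low IL-7, 1531 did, 398 higher and 1133 lower (limma's adjusted p, n = 3 per group).

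Among these, 3 probe sets that name the constant segment of the kappa light chain along with other segments stood out in the IRF4 arrays. The first rose with IRF4 by 5.01 (SE 0.16, limma's adjusted p = 3.96e-08) to 12.02 ± 0.36 (SD, n = 3), another by 5.67 (SE 0.14, adjusted p = 4.97e-09) to 12.68 ± 0.24, and the last by 6.04 (SE 0.14, adjusted p = 3.21e-09) to 12.03 ± 0.24. All 3 IRF4 arrays lay above all others for each. In high IL-7 the last of them lay below the intensity of the filter and is not known to be above background, so the sizes of its changes against high IL-7 depend on the added pseudocount. In low IL-7 the probe sets rose, in that order, by 0.52 (adjusted p = 0.0387), 1.13 (adjusted p = 0.000155) and 1.76 (adjusted p = 5.26e-06). The difference between IRF4 and low IL-7 was 4.49, 4.54 and 4.28 (adjusted p from 1.79e-08 to 4.87e-08). These probe sets match several kappa transcripts, so the signal is not assigned to 1 gene. Of the kappa probe sets above the filter that name 1 gene, 2 rose with IRF4 and 5 did not pass. A probe set of Igk rose by 0.63 (adjusted p = 0.00422), to 0.84 above low IL-7 (adjusted p = 4.63e-05). In low IL-7 this probe set lay below the intensity of the filter and is not known to be above background. The size of that difference thus depends on the added pseudocount. Igkv8-30 rose by 6.04, and its probe set can match several transcripts as well, so it does not single out a segment.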

How the results depend on the processing

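The stromal covariate, leaving out the 2 arrays with low 18S signal, the block fit in the 6 paired arrays, the scalings of the lists, the division of the high IL-7 arrays and the check of array weights were chosen after seeing the data. Quantile normalization, 75th percentile scaling, filters, pseudocounts, the choice of probe sets, the variance model, the replicate block and the 2 added settings kept all 4 counts of changed genes within 1.5 times their reported size. Over these settings low against high IL-7 gave 4416 to 5131 genes, IRF4 against high IL-7 gave 277 to 464, IRF4 against low IL-7 gave 4256 to 5177 and the genes changed the same way numbered 168 to 270. A scaling moved the median of all genes by less than 0.1 and the share of rises from 47.6% to at most 49.5%, from 65.4% to 71.8% and from 51.3% to 55.2% in the 3 comparisons.

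Larger moves came from 5 settings. With array weights the counts were 8266, 3248, 7810 and 1897 for the same way. In 20 random regroupings of residuals with the group means removed, 13 weighted fits and 1 unweighted fit called over 100 genes in a comparison, at most 5086 and 935, so the larger counts are not stronger evidence. The 935 of the 1 unweighted fit also exceeds the 376 genes called with IRF4 against high IL-7. A count of that size can thus arise in a regrouping without any effect. A change of at least 2-fold left 854, 105 and 729 genes, by its construction. With only the 6 arrays of the 2 groups, IRF4 against high IL-7 gave 222, from fewer arrays for the spread. An estimated correlation left 3 of 39 list calls. Correlation between members is not the only reason for the losses, since p also rose where the estimate lay below the preset 0.01. For the NF-kB list with IRF4 against high IL-7 the estimate was -0.0374. Its unadjusted camera p was 0.0277 with the preset correlation and 0.0563 with the estimated one. With no high IL-7 array shared between its 2 comparisons, the genes changed the same way numbered 142, 132 and 99 when replicate 1, 2 or 3 alone was the control of low IL-7, and 127, 55 and 71 when it alone was the control of IRF4. These fits have fewer control arrays and none shared, so the cause of the lower counts is not separated.

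Leaving out single arrays gave 3789 to 5119 genes in low against high IL-7, 191 to 615 with IRF4 against high IL-7, 3567 to 4912 with IRF4 against low IL-7 and 112 to 304 changed the same way. The extremes for IRF4 against high IL-7 came without IRF4 replicate 2 (191) and replicate 1 (615), with 204 without high IL-7 replicate 3. The fewest genes changed the same way came without the last array (112) and IRF4 replicate 2 (113), and the cause was not tested. The rise of the dimmer Irf4 probe set ranged from 2.11 to 2.71, the calls of named genes from 352 to 411 against 385, and the list calls from 35 to 42. Of the named calls, 143 of 158 in low against high IL-7, 54 of 77 with IRF4 against high IL-7 and 138 of 150 with IRF4 against low IL-7 were kept without any 1 array.

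In 3 cases a list reversed. In IRF4 against high IL-7 the interferon list had a median of -0.16 (adjusted p = 0.497) without IRF4 replicate 3 and -0.26 (adjusted p = 0.521) without the 2 arrays with low 18S signal. Over all single arrays left out, its median ran from -0.16 to 0.46. The test of the stromal list pointed up with the stromal covariate (median -0.038, adjusted p = 0.822), as the covariate was built from that list. Both reversals of the interferon list leave out IRF4 replicate 3, and the cause was not tested. In that comparison the preset calls of the progenitor, NF-kB, chemokine receptor and interferon lists were also lost under both scalings (adjusted p = 0.053 to 0.156) and that of the replication list under quantile normalization (adjusted p = 0.13).

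With the replicate number as a block the counts were 4922, 436, 4769 and 244 for the same way, and 5891 for low against high IL-7 in the 6 paired arrays alone. In low against high IL-7 the block over all 9 arrays changed the calls of Bak1, Col3a1, Col6a1, Igk, Cd74, Cd8a, Fcmr and Igll1. It changed the call of no other named gene or list. The IRF4 arrays share only numbers with the others (r = -0.353, -0.105 and -0.366 with high IL-7, and 0.015, -0.082 and -0.145 with low IL-7), and the block there left 35 list calls in all. No detection values were used, so the signal over background limits what can be said of dim probe sets.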

Other observations

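The gene families in the next paragraph, the tests of myeloid, dendritic and mature B cell RNA that of RNA quality and 2 sets of splits were chosen after the results were seen, the stromal covariate and the quantile normalization of the lists after seeing the data but before their own values, and the other tests before.

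Beyond the fixed lists, 13 gene families were counted. In low IL-7, 16 of 17 aminoacyl-tRNA synthetase genes, which charge tRNAs, fell (median -1.18), with Cars at -1.82 (SE 0.16) and Yars at -1.58 (SE 0.14). So did 59 of 75 mitochondrial ribosomal protein genes (median -0.63), all 8 genes of the chaperonin CCT (median -0.62), 24 of 37 proteasome genes (median -0.33), 25 of 38 translation initiation factors with 3 up (median -0.34) and 19 of 32 respiratory complex I genes with 2 up (median -0.28). Of 45 cytosolic ribosomal protein genes 14 fell. Lysine demethylases rose in 9 of 15, such as Kdm5b (1.07, SE 0.35) and Kdm3b (0.65, SE 0.09), and histone genes in 7 of 16 with 1 down, such as H2az2 (1.24, SE 0.05). Of 26 autophagy genes 9 rose and 3 fell, and of 14 regulators of G protein signalling 3 rose, Rgs2 by 2.69 among them, and 1 fell. Of 16 vacuolar ATPase genes 1 rose, Atp6v1d (0.79), and 2 fell, and of 23 semaphorins and plexins 5 fell, such as Sema7a (-1.64). With IRF4 in high IL-7, Rgs2 (1.64) and Atp6v1d (0.38) rose, Plxnd1 (-1.13) and Sema7a (-0.73) fell and no autophagy gene passed. In that comparison 3 histone genes rose, H2az2 (0.41), H3c4 (0.94) and H3c7 (0.92), and 1 initiation factor, Eif4a2, fell (-0.26). With an estimated correlation no family passed camera in either comparison (adjusted p = 0.226 or higher).

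Ribosome biogenesis genes fell in 30 of 30 and mitosis genes rose in 22 of 29 in low IL-7, with adjusted p = 0.0875 and 0.233 with an estimated correlation. A scaling factor for an array moves all genes alike, so it does not explain the distance between medians of -1.37 and 0.43, beside 0.02 for all genes. Under quantile normalization, less the median of all genes, the ribosome biogenesis and mitosis medians were -1.33 and 0.49. Both are relative to the other genes of an array, so a change in RNA per cell, which could alter either sign, was not tested. RNA of stromal cells, as far as the mean of the 19 stromal markers measures it, does not account for the distance either. With the stromal mean as a covariate the ribosome biogenesis median was -1.37 and the mitosis median 0.42. Stromal RNA that this mean does not follow is not excluded. The low dose of IL-7 thus stays as a hypothesis for the cause, found and tested on the same data.

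MHC class II genes rose with IRF4 in 5 of 9 and maturing B cell genes in 9 of 16, with adjusted p = 0.0882 and 0.124 with an estimated correlation. RNA of myeloid or dendritic cells would bring their abundant transcripts, but the highest upper 95% limit of the log2 changes of Lyz2, Csf1r, Tyrobp and Itgax was 0.26. Of the fixed list of 13 myeloid markers, though, Ctss rose by 1.29 along with the MHC class II genes, while Fcer1g fell by 1.40. RNA of mature B cells cannot be told apart from a rise within the pre-B cells: 2 of 16 maturing B cell markers, Cd72 and Cd9, fell, which is too few to decide. The IRF4 put back into these cells may also be the cause. No array here separates it from a change in the mix of cells or from the means of putting it back.

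Stromal genes differed between arrays of 1 group. Their deviations from the group means had a median pairwise correlation of 0.73 over 19 genes, above the highest of 1000 random lists of the same size (0.454). Stromal RNA in some cultures would give this, but so would any genes that vary together. The correlation that camera estimated was 0.65 for the stromal list, 0.80 for the interferon list and 0.64 for the cholesterol list. Passing random lists thus does not single out stromal RNA. The 18S control signal was lower in high IL-7 replicate 1 (6.53) and IRF4 replicate 3 (6.41) than in the other arrays (7.70 to 8.49). A difference in RNA quality cannot be told apart as a further source, since over 9 arrays the stromal and 18S deviations had Pearson's r = 0.633 and Spearman's rho = 0.517 (exact permutation p within groups 0.236 and 0.292, two-sided, 216 arrangements), and r = 0.343 without the 2 arrays farthest from the median 18S signal. The count of genes changed with IRF4 against high IL-7 was 306 with the stromal covariate and 277 without the 2 arrays with low 18S signal.

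Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. In low against high IL-7 the real split gave 4783 genes and the highest other 0, so 1 of 10 splits gave as many. The 3 others that part all 3 pairs gave 0 genes, as did the 6 that part 1 pair. All of these mix the 2 doses, which puts the difference between the doses into the spread. Their counts of 0 were thus nearly fixed in advance and give the 4783 no support. With IRF4 against high IL-7 the real split gave 376 and the highest other 131 (1 of 10), the latter setting high IL-7 replicate 1 with IRF4 replicates 2 and 3, the arrays of these groups with the lowest stromal means. With IRF4 against low IL-7 it gave 4651 and the highest other 0 (1 of 10). The other splits there mix 2 groups that lie far apart, so that 0 was nearly fixed in advance as well. For the fixed lists the real splits gave 10, 18 and 11 list calls and the highest others 13, 10 and 11, with 6, 1 and 3 of the 10 splits giving as many. For the genes changed the same way, 4 of 100 splits drawn from the 9 arrays gave as many as the real 213, the highest other 3724. These splits moved arrays without regard to the pairs. Of 100 that part all 3 pairs, chosen after the results were seen, 3 gave as many, the highest other 3495. Of the others as large, 3 in the first draw and 2 in the second had the 3 low IL-7 arrays as the shared control, and without such splits the highest in the first was 14. The share under 0.05 thus mainly shows how far these arrays lie from the rest. With the low IL-7 arrays kept together and the other 6 rearranged, also chosen afterwards, 1 of 20 arrangements gave as many and the highest other gave 179, so there a chance arrangement of the IRF4 and high IL-7 arrays is not excluded.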
